A study of Mus musculus with 72 samples.

How the data were processed

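Input and IP libraries were made from the same RNA of brain, liver and testis of mice given water, VB2, VB6 or VB12, with 3 mice in each of 4 treatments. Per the labels' protocols, 1.8 µg of polyadenylated RNA was broken into fragments of about 150 nt, an adapter with a barcode was ligated to each sample's fragments, and barcoded samples were pooled. Of the pool, 10% was kept as input and the rest was immunoprecipitated with an antibody against m6A, and both were sequenced as paired ends of 150 bp, per the labels' protocols. Which samples shared a pool is not given in the sources used here. Trim Galore, fastp 0.23.4 and FastQC and the mouse genome build mm39 are named per the submitters' processing notes, and the aligner and the counting tool are not given in the sources used here. The deposited files hold whole-number counts per gene, without normalization, for 50763 gene names in each of 72 files. No tissue, treatment or library was left out. The counts carry no molecular identifiers, so that PCR copies are counted as separate reads. Of the gene names, 46107 matched a symbol in a RefSeq table of the assembly GRCm38.p6, which was used for names only and from which no coordinates were taken.

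Counts were normalized by TMM and tested with edgeR 4.0.16 in R 4.3.3 with the quasi-likelihood F test, with Benjamini-Hochberg adjustment over the genes of each comparison and a threshold of 0.05 on the adjusted p. Genes were kept by edgeR's filterByExpr on the groups. Expression was tested on the 12 input libraries of a tissue with the 4 treatments in one fit and each vitamin set against water. m6A was tested on the input and IP libraries of a tissue with a block for each mouse, as the difference between vitamin and water in the log2 ratio of IP to input. Enrichment in water mice is that ratio itself. Differences of these effects between tissues were tested on all input libraries, or on all 72, with terms for tissue by treatment. The SE is the absolute log2 change divided by the square root of F. Library sizes in the fits were the totals over the genes kept, and the CPM of single genes were computed after TMM. Summed CPM and percents for transcripts of other tissues used the totals of the deposited counts, without TMM.

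The genes named were set by a rule fixed before the data were examined, as were the tests, the gene lists and the alternatives tried. The rule took, in each comparison, genes with a symbol that is not a predicted gene or pseudogene, an adjusted p under 0.05, at least 1 CPM in the higher group and no overlap between the 3 libraries of one group and the 3 of the other, and of these the 6 largest rises and the 6 largest falls. For m6A the input had to reach 1 CPM in both groups, for enrichment 10 CPM, and where no gene passed, the 3 genes with the smallest p were given. Of the gene lists, up to 4 members with the smallest p were written out, and called members of the m6A machinery and of the vitamin lists always. In all, 50 lists of 1044 genes were fixed, covering the vitamins and m6A, metabolism and stress, cell types of each tissue and transcripts of other tissues, and 49 of them entered a test. Each list was tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists and 3 vitamins of a tissue and measure. Of 528 list tests, 92 passed, 7 with the correlation estimated from the data and 27 with fry, which asks whether a list's genes move on balance one way. Genes were assigned to another tissue where they were at least 20 times more abundant there and reached 50 CPM.

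The replicate numbers pair input and IP, which come from the same mouse. The deviations of same-numbered input and IP libraries from their group means correlated over 0.1 in 36 of 36 pairs, with a median of 0.452. All 72 pairs of replicates within a group differed by more than sampling noise, with a chi-square over degrees of freedom of at least 5.43. Each fit was tested on simulated counts with 200 changed genes. For VB6 against water, genes changed 2-fold were recovered in 89.6% of cases in brain, 7.46% in liver and 80.6% in testis for expression and in 83.6%, 2.99% and 53.7% for m6A, and genes changed 4-fold in 72.7% for expression and 42.4% for m6A in liver. The fits between tissues, tested on 2000 genes, recovered 70.1% and 43.3% at 2-fold for VB6. Alternatives were RLE size factors, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, a fit to the groups compared alone, the replicate number as a block or no block, and each replicate left out. Comparisons restricted to genes most abundant in the tissue tested, and those without the shallowest library of liver VB12 and of testis VB6, were added after the data were seen. Shared calls of comparisons with the same water mice were set against 20 simulations for expression and 5 for m6A with no effect. Totals of IP over input were compared by exact permutation of the mice. Other splits of the mice were counted with edgeR for expression and with limma for m6A and for differences between tissues, with 100 splits drawn where there were more.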

Results

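Methylation of mRNA was measured in the brain, liver and testis of 6-week-old male C57BL/6J mice, an inbred laboratory strain, given water, vitamin B2 (riboflavin, VB2), vitamin B6 (VB6) or vitamin B12 (VB12) for 14 days. The doses were 50 mg/kg for VB2 and VB6 and 25 mg/kg for VB12. From each mouse and tissue there was an input library, which measures expression, and a library of fragments immunoprecipitated (IP) with an antibody against N6-methyladenosine (m6A), the methyl mark on adenosines of mRNA. The 72 libraries formed 24 groups of 3 mice, so that each vitamin could be set against water within each tissue, for expression and for m6A. The question, as the design states it, was how the vitamins act on m6A in tissues of the nervous, digestive and reproductive systems.

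Brain input libraries held 16554647 to 34163371 counts in water, 30806288 to 34256386 in VB2, 19086203 to 38274857 in VB6 and 26309671 to 30971046 in VB12. Brain IP libraries held 12736279 to 23716216 counts in water, 21647968 to 26309063 in VB2, 16667283 to 33877112 in VB6 and 22956016 to 27663071 in VB12. Input libraries of liver held 2190517 to 5634777 counts in water, 2686123 to 12220999 in VB2, 2084011 to 7624861 in VB6 and 869170 to 6396986 in VB12. IP libraries of liver held 1367337 to 2686458 counts in water, 1510747 to 4762380 in VB2, 4075219 to 11049044 in VB6 and 746215 to 6005741 in VB12. Testis inputs held 20904091 to 41490695 counts in water, 29007700 to 52726001 in VB2, 11141393 to 41774982 in VB6 and 23728141 to 39824432 in VB12. Testis IP libraries held 8642782 to 12884842 counts in water, 9392748 to 17762281 in VB2, 5037892 to 21003940 in VB6 and 15453579 to 20242335 in VB12. In the text, levels are mean CPM (counts scaled by library size) ± SD over 3 mice and changes are log2 differences ± SE, with adjusted p from edgeR's quasi-likelihood test over all genes tested. An m6A change is the vitamin's difference from water in the log2 ratio of IP to input of a transcript.

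**Figure D1:**
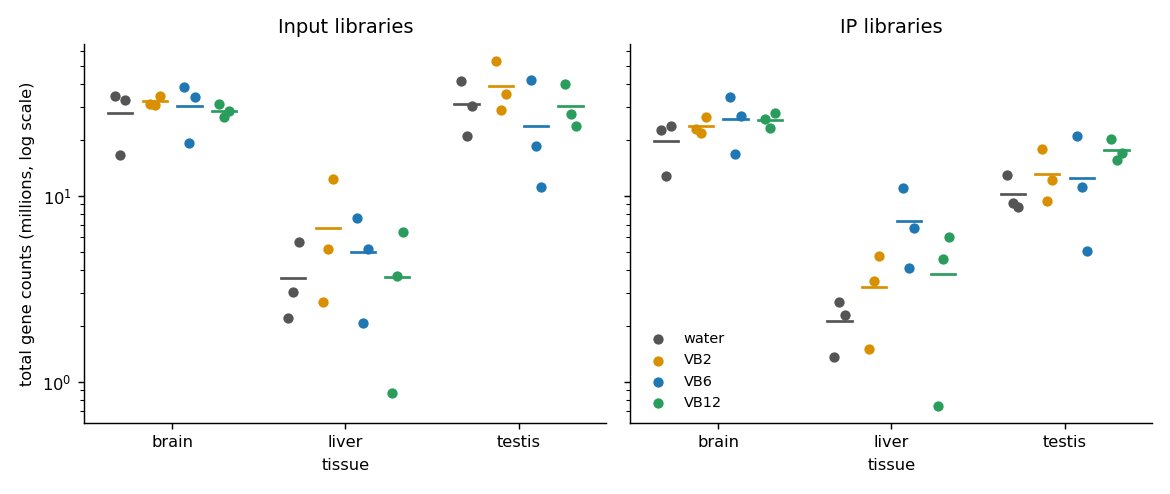
Total counts per library on a log axis, by tissue, library type and treatment; points are single libraries and bars are means of 3 mice. Most liver libraries lie below those of brain and testis, and their ranges overlap those of testis.

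Testis transcripts in brain, and brain transcripts in liver and testis, stood at higher mean levels in the water and VB2 libraries than in the VB6 and VB12 libraries. A list of 14 testis transcripts, among them the protamine Prm2, which packs sperm DNA, summed to 112 ± 20.2 CPM in brain inputs of water mice and 108 ± 31.7 CPM in VB2 mice. The sums were 19.6 ± 1.96 CPM in VB6 and 20.7 ± 0.4002 CPM in VB12 brains. Genes at least 20 times more abundant in brain than in liver summed to 2.02 ± 0.787% of their brain level in liver inputs of water mice. These sums were 1.81 ± 0.887% in VB2, 0.735 ± 0.0461% in VB6 and 0.733 ± 0.0753% in VB12. In liver IP libraries these shares were 6.45 ± 3.52%, 5.75 ± 4.36%, 0.937 ± 0.118% and 0.852 ± 0.0805%. Brain genes in testis inputs stood at 1.83 ± 0.0242% in water, 1.804 ± 0.0776% in VB2, 1.61 ± 0.175% in VB6 and 1.59 ± 0.07298% in VB12, where single libraries overlapped. In testis IP libraries they stood at 2.37 ± 0.289% in water, 2.35 ± 0.247% in VB2, 1.66 ± 0.192% in VB6 and 1.62 ± 0.127% in VB12. Of liver genes in brain, 247 of 522 were higher in water than in VB6 and VB12 inputs, of liver genes in testis 266 of 642 and of testis genes in liver 651 of 1593, against 1073 of 1168 testis genes in brain. In each of the 6 sets of 12 libraries, the first principal component placed the 6 libraries of water and VB2 apart from the 6 of VB6 and VB12 and held 21.6% of the variance in testis inputs to 44.1% in liver IP libraries. In testis inputs VB6 replicate 3 lay at -87.2 on it, the other 5 libraries of VB6 and VB12 at -5.47 to 4.57 and those of water and VB2 at 11.3 to 18.7. In liver inputs VB12 replicate 1 lay at -107, so that these shares also hold the distance of single libraries.

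**Figure D2:**
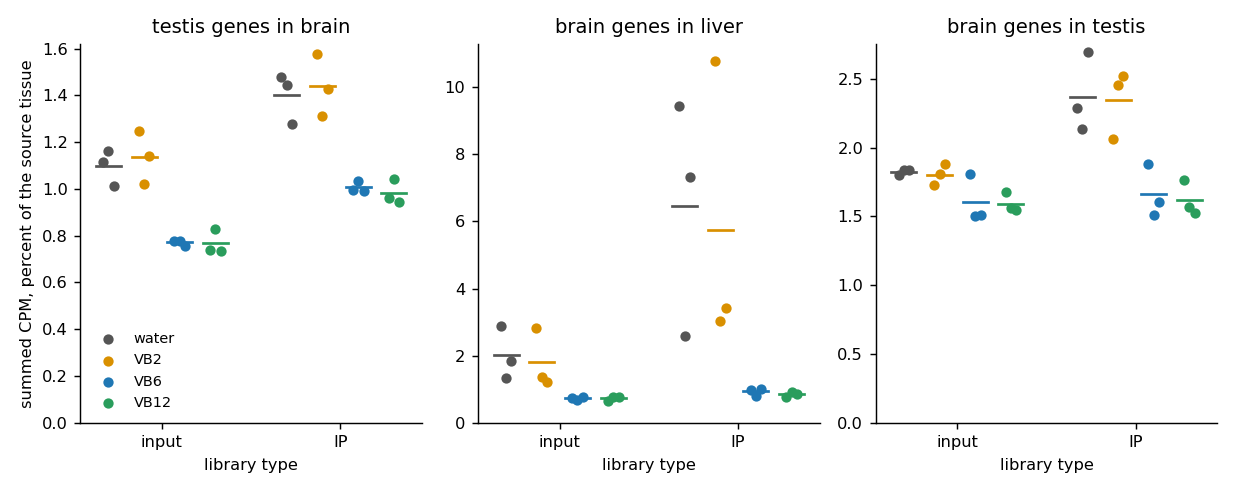
Summed CPM of genes of a source tissue in another tissue, as percent of their level in the source tissue, by treatment; points are single libraries and bars are means of 3 mice. The points of VB6 and VB12 lie low for testis genes in brain and for brain genes in liver, and those of inputs overlap for brain genes in testis.

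In water mice, IP enriched and depleted many transcripts in each tissue. In brain, 8539 transcripts were enriched in IP and 8312 were depleted out of 22535 tested. Of transcripts with at least 10 CPM in input, the largest enrichment in brain was that of Eid2 (3.36 ± 0.083), Ier5l (3.10 ± 0.10), Tmem121 (3.06 ± 0.085), Gemin7 (2.99 ± 0.076) and Lyset (2.93 ± 0.089), in log2 IP over input. Transcripts with large depletion included Rpl10 (-3.80 ± 0.25), Alg1 (-3.65 ± 0.22), Stab1 (-3.45 ± 0.23) and Lama5 (-3.33 ± 0.21). Rpl10 encodes a ribosomal protein with near-identical copies in the genome, which makes its value uncertain. Liver had 2584 enriched and 2680 depleted of 15446, led by Mup13 (4.04 ± 1.16), Ccdc85b (3.51 ± 0.20), Rpp25l (3.12 ± 0.25), Fam124a (3.10 ± 0.20) and Pth1r (3.09 ± 0.23) above 0 and by Eml3 (-4.80 ± 0.82), Stab1 (-4.76 ± 0.52), Gstp2 (-4.73 ± 0.30) and Wwtr1 (-4.34 ± 0.71) below it. Mup13, past the threshold in 4 of 9 alternatives, and Gstp2 belong to families of near-identical genes. Brain genes made up 560 of the enriched and 1 of the depleted transcripts in liver and 475 and 97 in testis. Testis had 8553 enriched and 7880 depleted of 26882, with Arl9 (3.13 ± 0.079), Rhox8 (2.94 ± 0.13), Eid2 (2.91 ± 0.10) and Rpp25l (2.90 ± 0.11) at one end and Entpd4b (-3.79 ± 0.98), Insl3 (-3.21 ± 0.15), Uba1y (-3.10 ± 0.22) and Chpt1 (-2.95 ± 0.23) at the other. Insl3 is a peptide hormone of Leydig cells.

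Enrichment in water mice differed between tissues for many transcripts. It was higher in brain than in liver for 3646 genes and lower for 4326 of 30553 tested, with Abcc10 (4.72 ± 0.34), Klf11 (3.93 ± 0.55) and Inpp5e (3.47 ± 0.46) at the upper end and Cpe (-4.34 ± 0.27) and Ckb (-4.11 ± 0.28) toward the lower end. Cpe and Ckb are abundant in brain, and brain genes stood at 6.45 ± 3.52% of their brain level in liver IP against 2.02 ± 0.787% in liver input. Against testis, enrichment in brain was higher for 2927 genes, among them Kcnk10 (2.61 ± 0.28), Nalf1 (2.54 ± 0.20) and Tmem184c (2.52 ± 0.18), and lower for 2574, among them Cep20 (-3.28 ± 0.33) and Tspan6 (-3.18 ± 0.23). Between liver and testis, 3119 genes were more enriched in liver, such as Sqor (2.95 ± 0.23), Cpe (2.88 ± 0.28) and Tgfbi (2.88 ± 0.28), and 2710 in testis, such as Abcc10 (-3.84 ± 0.35), Tymp (-3.82 ± 0.31) and Polr3d (-3.18 ± 0.45). The number of genes that differed between brain and testis, 5501, was 3002 without water replicate 1, 3365 without water replicate 3 and 2165 without the block for the mouse.

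No single gene passed the test in brain for VB2. The smallest unadjusted p-values were those of Hba-a1, an alpha-globin (from 112 ± 20.7 to 67.2 ± 7.498 CPM, -0.73 ± 0.15), Fam216b (-1.29 ± 0.30) and Alas2, the erythroid enzyme of haem synthesis (-0.80 ± 0.19), each with an adjusted p of 0.9998. Erythroid genes as a group were lower in VB2 than in water brains, with a median log2 difference of -0.63 over 9 members (camera adjusted p = 5.40e-12, adjusted p = 0.0274 with an estimated correlation), and 5 of them passed adjusted over the list alone. Ribosomal protein genes (camera adjusted p = 2.16e-05, adjusted p = 0.995 with an estimated correlation) and genes of oxidative phosphorylation (camera adjusted p = 3.38e-05, adjusted p = 0.995 with an estimated correlation) also shifted under camera's preset correlation, by medians of -0.082 and -0.078. Of 21397 genes, 608 had an unadjusted p under 0.05 in edgeR, none passed after adjustment, DESeq2 called 1, and 56 passed without the filter on low counts. For m6A, edgeR called 0 of 22535 and DESeq2 0, with 488 under an unadjusted p of 0.05. Slfn2 (0.90 ± 0.26), Alx4 (0.90 ± 0.28) and Ppil4 (0.36 ± 0.12) had the smallest p among them, with an adjusted p of 1. The m6A count was 1 without water replicate 3.

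VB6 and VB12 brains held far lower levels of testis transcripts than water brains. Smcp, a protein of sperm mitochondria, was at least 247-fold lower in VB6 and at least 234-fold lower in VB12, with no count in the 3 libraries of either vitamin and 8.64 ± 2.38 CPM in water. Tnp1, a transition protein of spermatids, was at least 129-fold and 122-fold lower, and Spz1 at least 127-fold and 121-fold. Prm2 was at least 909.9-fold lower in VB12 and 1435-fold (95% interval 397 to 11858) lower in VB6. Further genes without a count were Tnp2 and Prr30 in VB6, at least 218-fold and 129.9-fold lower, and Crisp2 and Gk2 in VB12, at least 113-fold and 99.1-fold lower. These bounds set the water level against 3 counts over the group and, like the intervals, cover counting error only. Of the 14 testis transcripts, 12 fell in VB6 and 12 in VB12 (14 and 14 adjusted over the list alone). Their medians with genes at 0 set to the bound were -6.77 and -6.27 (camera adjusted p = 1.39e-148 and 7.51e-137, and adjusted p = 0.000504 and 0.000504 with an estimated correlation).

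In all, 5 genes rose and 355 fell in VB6 brains and 6 rose and 358 fell in VB12 brains, out of 21397. Testis genes made up 321 and 318 of these falls. The rises in VB6 were Gm2004, outside the naming rule and chosen after its values were seen, Idi1, an enzyme of isoprenoid synthesis (from 13.1 ± 1.08 to 18.5 ± 0.211 CPM, 0.49 ± 0.11, adjusted p = 0.02895), Lrrtm2, a synaptic adhesion protein (0.31 ± 0.078), Zfp62 (0.40 ± 0.087) and Tars3 (0.35 ± 0.081). In VB12 the rises were Gla, the lysosomal alpha-galactosidase A (0.49 ± 0.11, adjusted p = 0.0309), and the zinc-finger genes Zfp971 (0.60 ± 0.14), Zfp65 (0.59 ± 0.13), Zfp37 (0.52 ± 0.13), Zfp617 (0.47 ± 0.11) and Zfp62 (0.43 ± 0.086). Sod1, the cytosolic superoxide dismutase, fell in both, from 70.8 ± 7.45 to 37.3 ± 3.53 CPM in VB6 (-0.93 ± 0.10) and by a log2 change of -0.94 ± 0.10 in VB12, the 1 member of the 24 antioxidant genes that passed in each. Among 61 nuclear genes of oxidative phosphorylation, Ndufa1 (-0.47 ± 0.11 and -0.46 ± 0.11) and Atp5mc3 (-0.40 ± 0.093 and -0.41 ± 0.093) fell in both. Erythroid genes had a median of -0.41 in VB12 (camera adjusted p = 1.56e-05, adjusted p = 0.155 with an estimated correlation), with Hba-a1 called and 6 of 9 passing adjusted over the list alone. Microglial genes shifted in VB6 (camera adjusted p = 0.0128, adjusted p = 0.995 with an estimated correlation) and genes of striatal neurons in VB12 (camera adjusted p = 0.00769, adjusted p = 0.995 with an estimated correlation), with no member of either list called. For VB6 and VB12 the counts were 622 and 709 without the filter on low counts and 184 and 195 with a filter of 1 CPM in 3 libraries. Among the 9371 genes most abundant in brain, a restriction chosen after the data were seen, edgeR called 0 in VB6 and 0 in VB12, with 569 and 735 at an unadjusted p under 0.05. Calls past the threshold in under 50% of their alternatives were Lrrtm2 (1 of 13), Ndufa1 (5 of 12) and Tars3 (4 of 13) in VB6. This was also the case of Gla (6 of 13), Zfp37 (4 of 12) and Zfp617 (6 of 13) in VB12.

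m6A in brain changed for few transcripts. 5 rose and 16 fell in VB6, and 1 rose and 7 fell in VB12, out of 22535 tested. In VB6 the rises were those of Ppil4 (0.60 ± 0.12, adjusted p = 0.0487), Prpf38b (0.47 ± 0.086, adjusted p = 0.0307) and Srsf11 (0.47 ± 0.090, adjusted p = 0.0493), each linked to splicing, and of Arl9 and Gm31166, which lie outside the naming rule and were chosen after their values were seen. The largest falls in VB6 were those of Arf5 (-1.05 ± 0.14, adjusted p = 0.00369), Uxs1 (-0.87 ± 0.11, adjusted p = 0.00165) and Metrn (-0.83 ± 0.12, adjusted p = 0.00369), with Kars1 (-0.79 ± 0.12) and Otub1 (-0.65 ± 0.10), and of Gapdhs (-1.23 ± 0.22), the sperm form of glyceraldehyde-3-phosphate dehydrogenase. In VB12 the rise was that of Arl9, and Metrn (-0.82 ± 0.12, adjusted p = 0.00495), Uxs1 (-0.79 ± 0.11, adjusted p = 0.00495) and R3hdm4 (-0.61 ± 0.10, adjusted p = 0.0319) fell, followed by Otub1 (-0.60 ± 0.10), Ptges3 (-0.59 ± 0.10) and Capns1 (-0.56 ± 0.097). Testis genes made up 2 of the 5 rises and 3 of the 16 falls in VB6 and, with Arl9, 1 of 1 and 0 of 7 in VB12. Kars1 is the lysyl-tRNA synthetase and Metrn a secreted protein of the nervous system. Mitochondrially encoded mRNAs had m6A medians of 0.31 (camera adjusted p = 3.44e-05, adjusted p = 0.986 with an estimated correlation) and 0.38 (camera adjusted p = 1.07e-07, adjusted p = 0.986 with an estimated correlation), with no member called over all genes and 1 and 4 adjusted over the list alone. Genes of oxidative phosphorylation stood at -0.18 in VB6 (camera adjusted p = 0.000125, adjusted p = 0.986 with an estimated correlation). With RLE size factors in place of TMM, the counts were 10 higher and 16 lower in VB6 and 3 and 9 in VB12. For VB6 and VB12 they were 83 and 44 with DESeq2, 147 and 86 without the filter on low counts, 1 and 1 in fits to the groups compared alone and 2 and 0 without the block for the mouse. Under limma, the real split of the mice gave 1 and 0 genes and the highest other split 1 and 1. The VB6 count was 3 and 3 without VB6 replicates 1 and 3 in turn and 9 without water replicate 2. The VB12 count was 2, 2 and 1 without VB12 replicates 1, 2 and 3 in turn and 2 and 14 without water replicates 1 and 3 in turn. Among the named calls, past the threshold in under 50% of alternatives were Gapdhs (5 of 12), Ppil4 (5 of 12) and Srsf11 (5 of 12) in VB6. The same held for Capns1 (4 of 12), Otub1 (6 of 13), Ptges3 (5 of 12) and R3hdm4 (6 of 13) in VB12.

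In VB2 livers 15 genes differed from water, 7 upward and 8 downward, out of 13854. Nr1d2, a repressor of the circadian clock, rose from 18.7 ± 6.94 to 83.6 ± 1.57 CPM (2.18 ± 0.27, adjusted p = 0.000475), as did Clec2h (3.10 ± 0.56), Arid5b (1.69 ± 0.22), Retreg1 (1.32 ± 0.22), Rapgef4 (1.25 ± 0.23) and Wsb1 (1.16 ± 0.20). The falls included Cdkn1a, the cell-cycle inhibitor p21 (from 22.4 ± 2.38 to 2.18 ± 1.64 CPM, -3.19 ± 0.41, adjusted p = 0.000475), Ppard, a nuclear receptor of fatty acids (-2.67 ± 0.38), Paxx (-1.87 ± 0.29), Tymp (-1.52 ± 0.29) and Abca2 (-1.15 ± 0.23). Of 20 clock genes, 1 rose, 0 fell and 19 did not pass (6 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00888, adjusted p = 0.1999 with an estimated correlation). Interferon response genes lay lower, with a median of -0.48 over 27 and no member called (0 higher and 3 lower adjusted over the list alone; camera adjusted p = 3.14e-06, adjusted p = 0.263 with an estimated correlation). Genes of xenobiotic metabolism had a median of 0.48 (camera adjusted p = 0.0006296, adjusted p = 0.917 with an estimated correlation), and Cdkn1a was the 1 called member of the glucocorticoid list. DESeq2 called 80 genes and the edgeR fit to these 2 groups alone 52. It was 126 without the filter on low counts. The count was 4 and 8 without VB2 replicates 1 and 3 in turn and 7 and 7 without water replicates 2 and 3 in turn. For m6A, edgeR called 1 of 15446, Gm6311, which lies outside the naming rule and was chosen after its values were seen. DESeq2 called 2, and 1054 had an unadjusted p under 0.05. Lyz2, the lysozyme of macrophages, came next (-3.69 ± 0.72, adjusted p = 0.0546). Then followed Ly96, with 2 IP counts in water and 92 in VB2 (75 and 142 in input) and an adjusted p of 0.169, and Orm2, an acute phase protein with close copies (-1.34 ± 0.32, adjusted p = 0.326). The m6A count was 3 without the filter on low counts, 2 with a filter of 1 CPM in 3 libraries and 0 without the block for the mouse. It was 0 without VB2 replicate 2.

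In VB6 livers 39 genes rose and 235 fell. Most of the falls were transcripts of brain genes. Gria2, a subunit of AMPA-type glutamate receptors, had no count in VB6 and 17.3 ± 10.3 CPM in water, at least 75.2-fold lower. Myt1l, Cdk5r2, Ppp2r2c, Gap43 and Nefm also had no count in VB6 and were at least 48.9-, 48.5-, 48.5-, 40.9- and 42.2-fold lower. Genes of brain made up 156 of the 235 falls and genes of testis 9. Of 10 brain transcripts on a fixed list, 7 fell (9 adjusted over the list alone), with a median of -5.14 with genes at 0 set to the bound (camera adjusted p = 2.79e-24, adjusted p = 0.1999 with an estimated correlation).

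The largest rises in VB6 livers under the naming rule were those of Slc16a5, a monocarboxylate transporter (from 0.437 ± 0.379 to 4.66 ± 2.35 CPM, 3.07 ± 0.76, adjusted p = 0.0369), Sftpa1 (2.09 ± 0.54), Tulp2 (1.78 ± 0.31), Snord13 (2.03 ± 0.50) and Cxcl9, an interferon-induced chemokine (1.67 ± 0.39), together with Cyp3a59 (2.05 ± 0.32), a cytochrome P450 of a family of close copies to which Cyp3a25 (1.27 ± 0.25) also belongs. Nr1h4, the bile acid receptor FXR, rose as well (0.77 ± 0.19, adjusted p = 0.0305). Single members of other lists fell, namely Gsr, glutathione reductase and a flavoenzyme (-1.07 ± 0.20, adjusted p = 0.00791), Tsc22d3, a glucocorticoid-induced gene (-1.13 ± 0.19), Pklr, the liver pyruvate kinase (-1.01 ± 0.23), Dnajb1, a heat shock protein (-1.45 ± 0.27), and Rbm15b, of the m6A writer complex (-1.45 ± 0.31). Interferon response genes had a median of 0.40 (camera adjusted p = 0.00197, adjusted p = 0.821 with an estimated correlation) and mitochondrially encoded mRNAs 0.81 (camera adjusted p = 0.000224, adjusted p = 0.925 with an estimated correlation), with 0 and 0 members called. Mitochondrial counts made up 13.7 ± 0.567% of liver inputs in water, 9.53 ± 1.73% in VB2, 20.1 ± 5.69% in VB6 and 20.1 ± 8.25% in VB12. The count was 55, 149 and 44 without VB6 replicates 1, 2 and 3 in turn and 88 and 129 without water replicates 1 and 3 in turn. Past the threshold in under 50% of their alternatives were Sftpa1 (5 of 14) and Slc16a5 (6 of 13).

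In VB12 livers 58 genes rose and 205 fell relative to water. Clock genes moved in both directions. Dbp, an output factor of the clock (from 1.23 ± 1.14 to 28.97 ± 5.399 CPM, 4.77 ± 0.74, adjusted p = 0.00569), Per3 (2.53 ± 0.35) and Nr1d2 (2.17 ± 0.28) rose, while Bmal1, which drives expression of these genes, fell (-1.69 ± 0.30, adjusted p = 0.00639). Nr1d2 rose about as much in VB2 (2.18 ± 0.27) against the same water livers. A difference of the water livers is not told apart from an effect of the vitamins there. Of 20 clock genes, 3 rose, 2 fell and 15 did not pass (6 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.00275, adjusted p = 0.1999 with an estimated correlation). Genes of the acute phase response, which the liver secretes during inflammation, had a median of 1.69 over 20 members (camera adjusted p = 1.45e-07, adjusted p = 0.917 with an estimated correlation). Of these, Socs3, an inhibitor of cytokine signalling, passed over all genes (from 10.8 ± 4.39 to 38.9 ± 3.97 CPM, 1.88 ± 0.34), against 14 higher and 1 lower adjusted over the list alone. Among 20 genes of xenobiotic metabolism, 3 rose (6 higher and 0 lower adjusted over the list alone; camera adjusted p = 2.59e-05, adjusted p = 0.792 with an estimated correlation): Por, the reductase of cytochromes P450 (1.55 ± 0.27), Cyp2c29 (1.06 ± 0.27) and Cyp3a25 (1.39 ± 0.26). Past the threshold in under 50% of its alternatives was Cyp2c29 (5 of 13).

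Mat1a, which makes S-adenosylmethionine, the methyl donor of m6A, rose in VB12 livers (from 1313 ± 192 to 3005 ± 607 CPM, 1.19 ± 0.24, adjusted p = 0.0162). Slc16a5 (4.39 ± 0.73) and Dnajc12 (2.18 ± 0.46) rose too. Falls outside the neuronal genes included Cdkn1a (-3.01 ± 0.45), Gsr (-1.16 ± 0.20), Tsc22d3 (-1.42 ± 0.20), Elovl3 (-1.91 ± 0.33) and Cdh5 (-1.59 ± 0.40). Neuronal transcripts without a count in VB12 were Camk2a, a synaptic kinase, Mobp, of myelin, Gria2, Myt1l, Trank1 and Cdk5r2, at least 74.1-, 64.9-, 55.4-, 35.98-, 37.8- and 35.7-fold lower. Brain genes made up 119 of the 205 falls, and of the 10 listed brain transcripts 7 fell (10 adjusted over the list alone; camera adjusted p = 3.27e-21, adjusted p = 0.1999 with an estimated correlation), with a median of -5.20 at the bound. The count was 99 and 78 without VB12 replicates 1 and 3 in turn and 64 and 78 without water replicates 1 and 3 in turn. For VB6 and VB12 the counts were 483 and 512 with DESeq2 and 706 and 696 without the filter on low counts. Among the 4821 genes most abundant in liver, a restriction chosen after the data were seen, edgeR called 31 in VB6 and 71 in VB12, with 707 and 850 at an unadjusted p under 0.05.

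**Figure D3:**
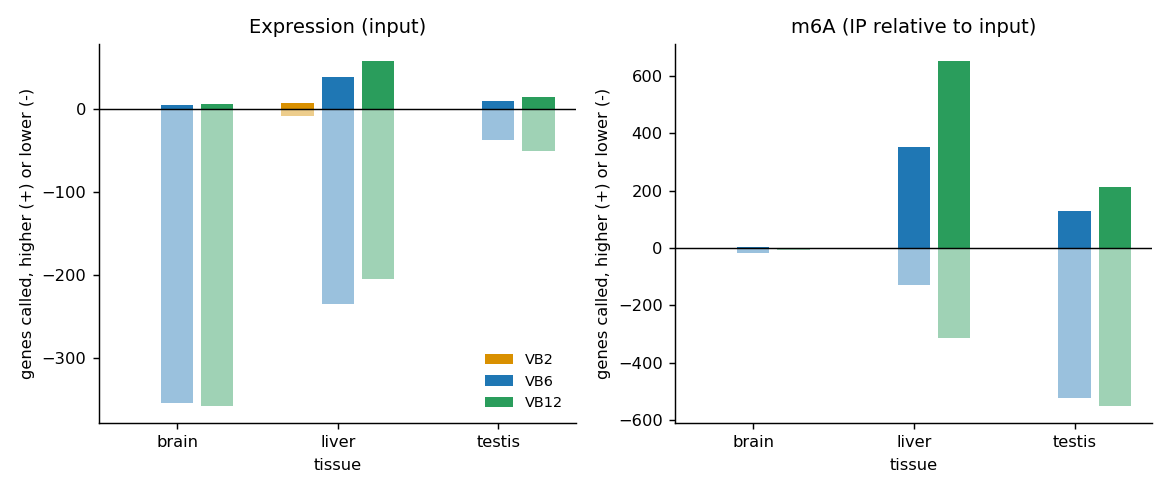
Genes past the threshold for each vitamin against water, by tissue, for expression and m6A; darker bars are genes higher in the vitamin and lighter bars genes lower. The counts for VB2 lie near 0 beside those for VB6 and VB12 in each tissue, except for m6A in brain, where all bars lie near 0.

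m6A in liver changed for 481 transcripts in VB6, 353 up and 128 down, and for 967 in VB12, 652 up and 315 down, out of 15446. Several transcripts with the largest rises were nearly absent from the water IP libraries, so their summed counts are given. All counts of the 3 IP libraries summed to 6340250 in water, 9740607 in VB2, 21821865 in VB6 and 11323730 in VB12. Ly96, which encodes a partner of the endotoxin receptor, had 2 IP counts in water and 132 in VB6 (75 and 89 in input) and 54 IP counts in VB12. Egfros had 0 IP counts in water and 120 in VB6 (92 and 246 in input) and 121 in VB12. In VB6, summed IP counts also went for Vtcn1 from 0 to 100, for Ifi213 from 0 to 102 and for Arhgdib from 3 to 218, and in VB12 for Tc2n from 0 to 25, for Nrg4 from 0 to 28 and for Wdr25 from 2 to 78. In VB2 livers, where none of these passed, the IP counts were 92 for Ly96, 106 for Egfros, 0 for Vtcn1, 9 for Ifi213, 43 for Arhgdib, 10 for Tc2n, 10 for Nrg4 and 43 for Wdr25. Mettl18, a histidine methyltransferase, rose by 4.03 ± 0.90 in VB6 (adjusted p = 0.00765). Falls in VB6 included those of transcripts abundant in neurons, Efr3b (-4.58 ± 1.34), Rtn1 (-4.27 ± 0.70), Aplp1 (-4.10 ± 0.93) and Pfn2 (-3.82 ± 1.06), and in VB12 those of Hcn2 (-3.98 ± 1.27), Slc22a17 (-3.96 ± 0.91), Oxct1 (-3.67 ± 1.06) and Dnm1, with 202 IP counts in water and 3 in VB12 (70 and 17 in input). Brain genes made up 31 of 128 falls in VB6 and 46 of 315 in VB12. As percent of their brain level, brain genes in liver IP went from 6.45 in water to 0.937 in VB6 and 0.852 in VB12. In liver inputs they went from 2.02 to 0.735 and 0.733. A loss of brain reads that is larger in IP than in input would lower the ratios of these genes. It was not told apart from a change in m6A. With RLE size factors the VB6 split was 254 up and 206 down, a shift of the median gene of -0.11. For VB6 and VB12 the counts were 311 and 668 in fits to the groups compared alone and 0 and 67 without the block for the mouse. Of the named calls, past the threshold in under 50% of alternatives were Arhgdib (6 of 13), Ifi213 (6 of 13), Pfn2 (6 of 13) and Vtcn1 (3 of 12) in VB6. This was also the case of Hcn2 (2 of 12), Nrg4 (3 of 12) and Tc2n (3 of 10) in VB12.

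Of 72 ribosomal protein mRNAs tested for m6A in liver, 11 fell in VB6 and 33 in VB12 and none rose (1 higher and 21 lower adjusted over the list alone in VB6, 0 and 43 in VB12). The medians were -0.43 (camera adjusted p = 7.53e-14, adjusted p = 0.1696 with an estimated correlation) and -0.89 (camera adjusted p = 5.25e-29, adjusted p = 0.0636 with an estimated correlation), and reads of ribosomal protein genes can be shared with their pseudogenes. Of 61 nuclear genes of oxidative phosphorylation, 16 fell in VB12 (24 adjusted over the list alone; median -0.54, camera adjusted p = 3.65e-10, adjusted p = 0.283 with an estimated correlation), while in VB6, 2 rose and 3 fell. Of 13 mitochondrially encoded mRNAs, 3 rose in VB6 and 6 in VB12 (5 and 8 adjusted over the list alone), with medians of 0.30 (camera adjusted p = 0.0296, adjusted p = 0.667 with an estimated correlation) and 0.83 (camera adjusted p = 1.27e-05, adjusted p = 0.599 with an estimated correlation). Mitochondrial counts made up 5.82 ± 1.09% of liver IP libraries in water, 5.62 ± 0.685% in VB2, 11.3 ± 3.999% in VB6 and 13.4 ± 3.604% in VB12. Of 24 genes of the m6A machinery, 2 rose in VB6 and 4 in VB12 (5 up and 0 down in VB6 and 4 up and 0 down in VB12 adjusted over the list alone). Zc3h13 of the writer complex (0.92 ± 0.23 in VB6 and 0.97 ± 0.24 in VB12) and the reader Ythdc1 (0.92 ± 0.25 and 0.99 ± 0.26) rose in both, and Rbm15 (0.92 ± 0.29) and Mettl5, a methyltransferase of ribosomal RNA with 3 IP counts in water and 44 in VB12 (99 and 56 in input), rose in VB12. Mettl5 also had 81 IP counts in VB6 and 45 in VB2 (110 and 173 in input), without a call there. Of 22 immediate early transcripts, 3 rose in VB6, Jun (1.83 ± 0.33), Ier2 (0.99 ± 0.26) and Dusp1 (1.25 ± 0.34), and 4 in VB12, with Myc (1.94 ± 0.55; 5 up and 0 down in VB6 and 5 up and 0 down in VB12 adjusted over the list alone). Of 22 genes of the unfolded protein and stress response, 3 rose in VB6, Sdf2l1 (1.45 ± 0.35), Calr (0.81 ± 0.21) and Dnajb11 (1.05 ± 0.30), and 5 in VB12 (4 up and 0 down in VB6 and 6 up and 2 down in VB12 adjusted over the list alone). Hsp90aa1 (1.03 ± 0.22 and 1.51 ± 0.22) and Hsp90ab1 (0.82 ± 0.21 and 1.29 ± 0.21) rose in both. Named calls that passed in under 50% of alternatives were Dnajb11 (5 of 13), Dusp1 (6 of 14) and Ythdc1 (5 of 13) in VB6. The same held for Rbm15 (3 of 13) in VB12.

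On the vitamin lists, m6A of Mat2a, the other S-adenosylmethionine synthetase, fell in VB6 (-1.08 ± 0.32) and in VB12 (-1.12 ± 0.33). In VB12, m6A also fell on Mat1a (-0.81 ± 0.21, adjusted p = 0.0112), Gamt (-1.08 ± 0.29), Aldh1l1 (-0.85 ± 0.23) and Nnmt (-0.89 ± 0.24). In all, 5 of 25 genes of the folate and methionine cycle fell in VB12 and 1 in VB6 (0 up and 2 down in VB6 and 0 up and 6 down in VB12 adjusted over the list alone). Flavoenzyme and riboflavin genes went both ways, with Gsr (1.20 ± 0.27), Maob (1.12 ± 0.29) and Slc25a32 (1.27 ± 0.34) up and Sqor (-1.19 ± 0.30) down in VB6, and in VB12 3 up and 3 down of 30, Gsr (1.03 ± 0.28), Maob (0.93 ± 0.29) and Slc25a32 (1.40 ± 0.35) against Sqor (-1.34 ± 0.31), Acadl (-0.94 ± 0.24) and Etfa (-0.92 ± 0.25) (3 up and 1 down in VB6 and 3 up and 4 down in VB12 adjusted over the list alone). Of genes tied to pyridoxal phosphate, the active form of vitamin B6, Hdc rose (1.55 ± 0.41 in VB6 and 1.997 ± 0.42 in VB12) and Agxt fell (-1.14 ± 0.25 and -1.27 ± 0.25) with both vitamins, and Alas2 fell in VB12 (-1.14 ± 0.30). Prdx6, a peroxiredoxin placed on the fixed cobalamin list, was the 1 called gene of that list, in VB12 (-1.10 ± 0.27). Its other members, Tcn2, Mmab and Mmut among them, were not called. Acute phase transcripts were split 3 up and 3 down in VB6 and 4 and 4 in VB12 (4 up and 4 down in VB6 and 5 up and 5 down in VB12 adjusted over the list alone). Of the clock, Rora (1.38 ± 0.25), Cry2 (1.46 ± 0.39) and Nr1d1 (1.35 ± 0.39) rose in VB6, and 2 rose and 1 fell in VB12 (3 up and 0 down in VB6 and 3 up and 2 down in VB12 adjusted over the list alone). The VB6 count was 112, 281 and 118 without VB6 replicates 1, 2 and 3 in turn and 214 without water replicate 1. The VB12 count was 594, 474 and 465 without VB12 replicates 1, 2 and 3 in turn and 630 without water replicate 1. Here the calls that passed in under 50% of alternatives were Cry2 (6 of 13), Mat2a (5 of 13), Nr1d1 (3 of 13) and Slc25a32 (6 of 14) in VB6. This was also the case of Maob (4 of 13) in VB12.

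**Figure D4:**
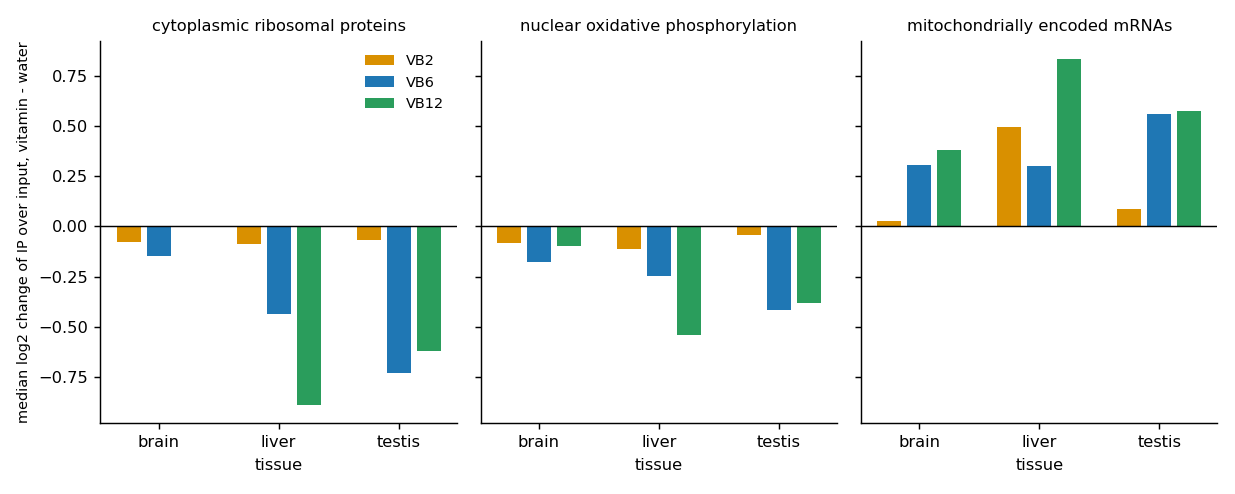
Median log2 m6A change against water of the tested members of each gene list, by tissue and vitamin; bars start at 0 and have no error bars. Ribosomal protein and oxidative phosphorylation genes lie below 0 and mitochondrially encoded mRNAs above 0 for VB6 and VB12 in testis.

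In testis, 1 of 26747 genes passed the test in VB2. Hba-a1 (-1.25 ± 0.22), Hbb-bs (-1.03 ± 0.20) and the mitochondrial COX2 (-0.49 ± 0.14) had the smallest p of genes with a symbol and did not pass, with an adjusted p of 0.156 for Hba-a1, an alpha-globin with a near-identical copy. Erythroid genes had a median of -0.034 over 9 (camera adjusted p = 5.63e-06, adjusted p = 0.213 with an estimated correlation), mitochondrially encoded mRNAs -0.27 over 13 (camera adjusted p = 4.84e-08, adjusted p = 0.213 with an estimated correlation) and genes of Leydig cells -0.13 over 18 (camera adjusted p = 0.000321, adjusted p = 0.496 with an estimated correlation). The gene called was Gm26689, which fell and was chosen after its values were seen. In all, 600 had an unadjusted p under 0.05 and DESeq2 called 3. The count was also 11 without the filter on low counts, 0 with a filter of 1 CPM in 3 libraries and 4 in fits to the groups compared alone. The count was 0 without VB2 replicate 1 and 2 without water replicate 2. For m6A, edgeR and DESeq2 called 0 and 0 of 26882, with 906 at an unadjusted p under 0.05. The smallest p were those of Chmp2a (-0.80 ± 0.17), Psmg4 (1.43 ± 0.30) and Pmm1 (0.93 ± 0.24), each with an adjusted p of 1. The m6A count was 31 without the filter on low counts and 1 in fits to the groups compared alone. The m6A count was 2 without VB2 replicate 3.

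In testis, 10 genes rose and 37 fell in VB6 and 15 rose and 51 fell in VB12 relative to water, out of 26747. Slc27a2, a transporter and acyl-CoA synthetase of fatty acids, rose in both, from 1.17 ± 0.114 to 4.67 ± 2.59 CPM in VB6 (1.90 ± 0.34, adjusted p = 0.0195) and by 1.64 ± 0.34 in VB12. Other rises in VB6 were those of Slc22a6, an organic anion transporter (2.08 ± 0.39), Dynlt2a2 (0.92 ± 0.17) and the respiratory chain subunits Ndufb9 (0.44 ± 0.089) and Cox5b (0.39 ± 0.084). The rises in VB12 included Bhmt1b (0.78 ± 0.16), H2bc22 (0.58 ± 0.12), Col22a1 (0.50 ± 0.10), the mitochondrial COX3 (0.88 ± 0.16) and the ribosomal Rpl21 (0.72 ± 0.12) and Rpl7 (0.38 ± 0.080), both with pseudogenes. Of the rises, 2 of 10 in VB6 and 8 of 15 in VB12 were genes most abundant in testis, against 54.8% of the genes tested. The falls were mostly genes of brain, 32 of 37 in VB6 and 49 of 51 in VB12. Vsnl1, a neuronal calcium sensor, was 52.7-fold (95% interval 14.3 to 439) lower in VB6 and 66.1-fold (95% interval 17.9 to 551) in VB12, and Snap25, of synaptic vesicle fusion, 85.1-fold (95% interval 28.8 to 416) lower in VB12. Camk2a fell in VB6 (-3.88 ± 0.33). Ddn (from 2.23 ± 0.493 to 0.09198 ± 0.09196 CPM) and Tubb4a (from 1.57 ± 0.643 to 0.0307 ± 0.0531 CPM) in VB6 and Ddn, Tubb4a and Gpr37l1 in VB12 (to 0.101 ± 0.11, 0.0886 ± 0.09096 and, from 1.06 ± 0.254, 0.0561 ± 0.0972 CPM) also fell, with single libraries of the vitamin at 0 counts, so that no fold is given. For VB6 and VB12 the counts were 102 and 161 with DESeq2, 199 and 337 without the filter on low counts, 30 and 40 with a filter of 1 CPM in 3 libraries and 67 and 105 with the replicate number as a block. Passing in under 50% of its alternatives was Cox5b (4 of 12) in VB6.

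Of 12 listed brain transcripts in testis, 4 fell in VB6 and 5 in VB12 (10 and 9 adjusted over the list alone), with medians of -1.24 (camera adjusted p = 3.95e-32, adjusted p = 0.00735 with an estimated correlation) and -1.07 (camera adjusted p = 1.03e-34, adjusted p = 0.00735 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.10 in VB6 with 2 of 61 called up (3 higher and 0 lower adjusted over the list alone; camera adjusted p = 4.84e-08, adjusted p = 0.213 with an estimated correlation) and 0.090 in VB12 with none called (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 6.62e-07, adjusted p = 0.239 with an estimated correlation). For ribosomal protein genes the medians were 0.13 (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.69e-08, adjusted p = 0.507 with an estimated correlation) and 0.14 (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.46e-09, adjusted p = 0.496 with an estimated correlation). Mitochondrially encoded mRNAs had a median of -0.28 in VB12, where COX3 rose (camera adjusted p = 0.000844, adjusted p = 0.496 with an estimated correlation). Genes of the epididymis, the duct beside the testis, had a median of 3.68 over 5 in VB12, with 4 higher adjusted over the list alone and none over all genes (camera adjusted p = 0.00507, adjusted p = 0.551 with an estimated correlation). Lcn8, listed among them, had 9801 counts summed over the VB12 inputs and 2 over those of water. Plin4, which coats lipid droplets, fell in VB6 (-1.52 ± 0.24). The VB6 count was 19 without water replicate 3. The VB12 count was 40 and 36 without VB12 replicates 2 and 3 in turn and 40 and 24 without water replicates 2 and 3 in turn. Among the 14667 genes most abundant in testis, a restriction chosen after the data were seen, edgeR called 1 in VB6 and 1 in VB12, with 1138 and 1359 at an unadjusted p under 0.05. Both calls were falls.

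Relative to the typical transcript, m6A in testis was called lower more often than higher. In VB6 it was lower on 525 transcripts and higher on 130, and in VB12 lower on 550 and higher on 212, out of 26882. Scaling by TMM centres these changes, so their balance does not show a fall over all transcripts. Total counts of IP over input lay 0.61 and 0.80 (log2) above water in VB6 and VB12 testes (exact permutation p = 0.1 for each). Slc27a2 (2.56 ± 0.61, adjusted p = 0.0265, and 2.54 ± 0.61), the plasma glutathione peroxidase Gpx3 (2.53 ± 0.32 and 2.34 ± 0.32) and Mir296 (2.31 ± 0.58 and 2.10 ± 0.55) had the largest rises in both. Further rises in VB6 were those of Cyp2e1 (2.26 ± 0.52), Pm20d2 (1.77 ± 0.42) and Napsa (1.76 ± 0.45). In VB12 they were those of ND4L (2.06 ± 0.45), Prodh (1.73 ± 0.45) and Speer1f (2.06 ± 0.51), a member of a family of near-identical genes. Genes of liver made up 9 of the 130 rises in VB6 and 10 of the 212 in VB12, and 487 of the genes tested. As percent of their liver level, liver genes in testis IP stood at 1.29 in water, 1.77 in VB6 and 1.25 in VB12. In testis inputs they stood at 1.47, 1.33 and 1.20. Reads of another tissue were not told apart from a change in m6A for these rises. The falls included those of neuronal transcripts, Tspan7 (-3.07 ± 0.38), Tspan2 (-2.90 ± 0.70), Gad1 (-2.49 ± 0.61), Syt1 (-2.45 ± 0.47), Cplx1 (-2.28 ± 0.44) and Gpm6a (-2.17 ± 0.36) in VB6 and Syt1 (-2.89 ± 0.45), Unc13a (-2.64 ± 0.51), Dnajc6 (-2.61 ± 0.40), Gpm6a (-2.54 ± 0.33) and Tspan7 (-2.49 ± 0.34) in VB12. Gad1 is a pyridoxal phosphate enzyme that makes the transmitter GABA. Genes of brain made up 34 of the 525 falls in VB6 and 56 of the 550 in VB12. As percent of their brain level, brain genes in testis IP went from 2.37 in water to 1.66 in VB6 and 1.62 in VB12. In testis inputs they went from 1.83 to 1.61 and 1.59. A loss of brain reads that is larger in IP than in input would lower these ratios. It was not told apart from a change in m6A. Of the 12 listed brain transcripts, 5 fell in VB6 and 6 in VB12 (10 and 9 adjusted over the list alone), with medians of -1.61 (camera adjusted p = 3.40e-15, adjusted p = 0.00357 with an estimated correlation) and -1.70 (camera adjusted p = 1.30e-16, adjusted p = 0.001702 with an estimated correlation). For VB6 and VB12 the counts were 342 and 364 in fits to the groups compared alone and 165 and 145 without the block for the mouse. The VB6 count was 245 and 309 without VB6 replicates 1 and 3 in turn and 315 and 414 without water replicates 1 and 2 in turn. The VB12 count was 278, 386 and 450 without VB12 replicates 1, 2 and 3 in turn and 411 and 389 without water replicates 1 and 2 in turn. The named calls that passed in under 50% of alternatives were Gad1 (5 of 11), Mir296 (5 of 12) and Napsa (6 of 13) in VB6. The same held for Mir296 (6 of 14) and Prodh (6 of 13) in VB12.

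Of 73 ribosomal protein mRNAs tested for m6A in testis, 34 fell in VB6 and 32 in VB12 and none rose (53 and 52 down adjusted over the list alone), with medians of -0.73 (camera adjusted p = 1.19e-55, adjusted p = 0.232 with an estimated correlation) and -0.62 (camera adjusted p = 4.98e-46, adjusted p = 0.256 with an estimated correlation). Of 61 nuclear oxidative phosphorylation genes, 16 fell in VB6 and 16 in VB12 (31 and 31 adjusted over the list alone), with medians of -0.42 (camera adjusted p = 1.19e-23, adjusted p = 0.273 with an estimated correlation) and -0.38 (camera adjusted p = 4.54e-25, adjusted p = 0.2602 with an estimated correlation). Meanwhile 6 of 13 mitochondrially encoded mRNAs rose in VB6 and 6 in VB12 (11 and 7 adjusted over the list alone), with medians of 0.56 (camera adjusted p = 9.15e-13, adjusted p = 0.246 with an estimated correlation) and 0.57 (camera adjusted p = 4.65e-11, adjusted p = 0.256 with an estimated correlation). Of 20 genes of elongating spermatids 6 and 8 fell (9 and 9 adjusted over the list alone; camera adjusted p = 2.85e-08, adjusted p = 0.0556 with an estimated correlation, in VB6), and of 21 genes of round spermatids 4 and 3 (camera adjusted p = 0.0014, adjusted p = 0.455 with an estimated correlation, in VB6). On the vitamin lists, Cd320, the receptor for transcobalamin (-0.46 ± 0.11 and -0.42 ± 0.11), and Kdm1a, a flavin-dependent histone demethylase (-0.44 ± 0.12 and -0.55 ± 0.12), fell in both, and Etfb (-0.86 ± 0.20) in VB12. Ythdf2, a reader of m6A, rose in VB12 (0.53 ± 0.14, adjusted p = 0.0372). Atf4, of the integrated stress response, fell in both (-0.60 ± 0.14 and -0.64 ± 0.14), with Ddit3 (-0.43 ± 0.11) and Creld2 (-0.46 ± 0.12) in VB12. Of these, past the threshold in under 50% of alternatives were Cd320 (4 of 13) and Kdm1a (3 of 13) in VB6. This was also the case of Cd320 (5 of 14), Creld2 (6 of 14) and Ddit3 (5 of 14) in VB12.

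Few genes differed between VB6 and VB12. Between them edgeR called 0 genes in brain, 7 in liver and 0 in testis for expression, with 411, 942 and 980 at an unadjusted p under 0.05, and 0, 0 and 2 for m6A, with 568, 321 and 489. The 2 m6A genes in testis were Gm21756 and Gm29740, outside the naming rule and chosen after their values were seen. A count of 0 does not show that the vitamins act alike. VB2 differed from VB6 in 377, 689 and 64 genes and from VB12 in 391, 124 and 67. For m6A these counts were 17, 359 and 477 for VB6 and 10, 727 and 516 for VB12. VB6 and VB12 shared 316 falls in brain, 137 in liver and 26 in testis, against 5.94, 3.48 and 0.0706 for independent lists and means of 0.15, 0.05 and 0.05 shared calls in simulations without any effect. They shared 305 rises and 101 falls of m6A in liver and 81 and 392 in testis, where independent lists give 14.9, 2.61, 1.03 and 10.7 and simulations means of 0 and 0.4. The covariance of their m6A changes across genes was 1.45 in liver against a simulated 0.391, and 0.365 against 0.165 in testis. For VB2 with VB6 and VB2 with VB12 it was 0.724 and 0.733 in liver against 0.398 and 0.396. In testis these were 0.237 and 0.248 against 0.164 and 0.163. The correlation of the m6A changes of VB6 and VB12 was 0.797 in liver and 0.705 in testis against a simulated 0.524 and 0.533. Those of VB2 with VB6 were 0.518 and 0.493 against 0.561 and 0.519. With VB12 the values of VB2 were 0.483 and 0.539 against 0.518 and 0.548. For expression the covariance of VB6 and VB12 was 0.6004 in brain, 0.8396 in liver and 0.123 in testis against 0.0535, 0.1099 and 0.0466. Both vitamins were set against the same 3 water mice, so part of the excess in shared calls can come from these. The simulated groups held no effect and no library sets, so few calls were possible in them. They do not bear on the cause of the shared calls.

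The effect of a vitamin was also compared between the tissues. For expression it differed in 20 genes for VB2, 1242 for VB6 and 1236 for VB12, out of 30130, and for m6A in 32, 1425 and 1254 out of 30553. Of the 1242 for VB6, 456 were genes of testis relative to brain and 454 genes of brain relative to liver, while 321 were called within brain, 210 within liver and 37 within testis. For m6A under VB6, 360 of 1425 were called within liver, 147 within testis and 12 within brain. The m6A count for VB6 was 591 with RLE size factors, 770 without the filter on low counts and 47 without the block for the mouse. The expression count for VB6 was 732 with a filter of 1 CPM in 3 libraries. The expression count for VB12 was 734 with a filter of 1 CPM in 3 libraries. The expression count for VB2 was 44 with RLE size factors, 65 without the filter on low counts and 66 with a filter of 1 CPM in 3 libraries. The m6A count for VB2 was 161 without the filter on low counts, 49 with a filter of 1 CPM in 3 libraries and 1 without the block for the mouse. The m6A count for VB12 was 67 without the block for the mouse. The expression count for VB2 was 13 and 10 without VB2 replicates 2 and 3 in turn and 10, 5 and 9 without water replicates 1, 2 and 3 in turn. The expression count for VB12 was 758 without VB12 replicate 3. The m6A count for VB2 was 12 without VB2 replicate 2 and 83 without water replicate 3. The m6A count for VB6 was 557, 942 and 579 without VB6 replicates 1, 2 and 3 in turn and 855 without water replicate 1. The m6A count for VB12 was 506 and 590 without VB12 replicates 2 and 3 in turn and 737 without water replicate 1.

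Total IP counts relative to input, which depend on pooling and sequencing as well as on m6A, were compared per mouse. The log2 ratio in brain was -0.48 ± 0.11 in water and -0.23 ± 0.085 in VB6 (2-sided exact permutation p = 0.1), and lay 0.31 above water in VB12 (exact p = 0.1). The difference from water was 1.35 for VB6 and 0.72 for VB12 in liver (exact p = 0.1 and 0.2) and 0.61 and 0.80 in testis (exact p = 0.1 for each). For VB2 it was 0.027, -0.20 and -0.014 in brain, liver and testis (exact p = 0.9, 0.7 and 1). With 3 mice against 3 the smallest p is 0.1, so that none of the 9 comparisons could pass, and the smallest value after Benjamini-Hochberg adjustment was 0.18.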

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

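Each test weighed here except that of the acute phase genes and the splits of the mice between tissues was chosen after the result was seen. Effects that differed between tissues were found for expression in 20, 1242 and 1236 genes for VB2, VB6 and VB12 and for m6A in 32, 1425 and 1254. Of 100 splits of the mice tested with limma, 1 for VB6 and 1 for VB12, the real split alone, gave as many genes for expression. The real splits gave 1335 and 1439 genes and the others at most 854 and 1019, a share under 0.05. The splits moved the mice of each tissue independently and others also called many genes. A split could keep or exchange the real groups in some of the tissues, though not in all. High counts in other splits can therefore come from the treatment itself. A structure of the samples other than the treatment is neither shown nor excluded by them. For m6A, 4 splits gave as many for VB12 (real 1815, highest other 2550), under the share of 0.05, while 6 did for VB6 (real 1624, highest other 1817), so that chance is not excluded there. For VB2, 31 splits for expression (real 83, highest other 275) and 69 for m6A (real 187, highest other 338) gave as many, and chance is not excluded. Some splits called several times more genes than the real one, as for expression with VB2. They too may hold the real groups in some tissues, so they do not settle whether the samples have another structure.

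Testis transcripts in brain and brain transcripts in liver and testis were lower after VB6 and VB12 than in water. Across genes, which are not independent replicates, the excess in water inputs tracked the level in the source tissue, with Spearman correlations of 0.655 over 1168 testis genes in brain, 0.5797 over 1276 brain genes in liver and 0.538 over 900 brain genes in testis, in line with reads or RNA of these tissues in the water libraries. The tissue's own genes made up 4.53% of the falls in brain against 43.8% of those tested. These shares were 4.84% against 54.8% in testis and 18.8% against 34.8% in liver. The pattern was picked for its transcripts of other tissues, so these shares cannot decide on a response of the tissue's own transcripts, which stays open. In the 6 liver IP libraries of water and VB2, counts of brain genes per count of the same-numbered brain library varied 0.242 times as much as counts per own count (ratio of log2 SDs), which is consistent with mixing between pooled or barcoded libraries, while in the 6 inputs the ratio was 0.771, which leaves mixing open there. The labels do not say which samples were pooled together, so that a set of water and VB2 libraries handled apart from VB6 and VB12 may account for this, and an effect of VB6 and VB12 on these transcripts stays open as untested.

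The m6A changes of VB6 and VB12 were shared in liver and testis. Transcripts of other tissues are argued against as the whole cause, since 51.8% of the called genes in liver were liver's own against 32.9% of those tested, and 57.7% against 54.5% in testis. A difference in overall IP efficiency would push changes along the enrichment of each gene, which held for 52.8% of called genes in testis and 66.6% in liver. Enrichment in water and the change against water share the water libraries, which pushes their signs apart. An even split is therefore no yardstick, and a difference in IP efficiency stays open in both tissues. Within the pairs water with VB2 and VB6 with VB12, 1 gene was called in liver and 2 in testis, against 1448 and 1417 calls of VB6 and VB12 against water. An effect common to VB6 and VB12 and a difference between library sets therefore cannot be told apart, because each library set would hold the same treatments.

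Acute phase genes were higher in VB12 livers, with a median log2 change of 1.69 over 20 members. The shallowest VB12 library, replicate 1, is argued against as the cause, since the median was 1.88 without it, a test fixed before the result was seen. Inflammation or handling of single mice stays open and was not tested, and camera with an estimated correlation gave an adjusted p of 0.917.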

How the results depend on the processing

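The restriction to genes most abundant in the tissue tested was chosen after the results were seen, and so was leaving out liver VB12 replicate 1 and testis VB6 replicate 3 as the shallowest libraries, which are among the libraries left out in turn. Genes changed 2-fold were recovered least in liver, in 7.46% of simulated cases for expression, where depth and spread between mice were not told apart. Of the results compared with RLE size factors, 28 of 30 stayed within 1.5 times their count, 11 of 21 with DESeq2 and 155 of 226 values with 1 replicate left out. Of values of single named genes and list members, 456 of 473 kept their side of the threshold with RLE size factors, 421 of 429 with DESeq2, 2000 of 2813 with 1 replicate left out and 130 of 341 without the block, and 0 changed direction when past the threshold. Of 458 such values past the threshold, 64 were past it in under 50% of their alternatives. The cause of each change listed here was not tested, except that fewer genes or fewer mice enter where genes or replicates are left out.

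Without the filter on low counts, the counts were 56, 622 and 709 for expression in brain (VB2, VB6 and VB12), 126, 706 and 696 for expression in liver (VB2, VB6 and VB12), 11, 199 and 337 for expression in testis (VB2, VB6 and VB12), 16, 147 and 86 for m6A in brain (VB2, VB6 and VB12), 3 for m6A in liver (VB2), 31 for m6A in testis (VB2), 65 for differences of expression between tissues (VB2) and 161 and 770 for differences of m6A between tissues (VB2 and VB6). With a filter of 1 CPM in 3 libraries they were 184 and 195 for expression in brain (VB6 and VB12), 0, 30 and 40 for expression in testis (VB2, VB6 and VB12), 2 for m6A in liver (VB2), 66, 732 and 734 for differences of expression between tissues (VB2, VB6 and VB12) and 49 for differences of m6A between tissues (VB2). DESeq2 called 1 for expression in brain (VB2), 80, 483 and 512 for expression in liver (VB2, VB6 and VB12), 3, 102 and 161 for expression in testis (VB2, VB6 and VB12), 83 and 44 for m6A in brain (VB6 and VB12) and 2 for m6A in liver (VB2). RLE size factors gave 44 for differences of expression between tissues (VB2) and 591 for differences of m6A between tissues (VB6). Fits to the groups compared alone gave 52 for expression in liver (VB2), 4 for expression in testis (VB2), 1 and 1 for m6A in brain (VB6 and VB12), 311 for m6A in liver (VB6) and 1, 342 and 364 for m6A in testis (VB2, VB6 and VB12). Restricted to genes most abundant in the tissue tested, the counts were 0 and 0 for expression in brain (VB6 and VB12), 31 and 71 for expression in liver (VB6 and VB12), 1 and 1 for expression in testis (VB6 and VB12), 6 for m6A in brain (VB6) and 409 and 458 for m6A in testis (VB6 and VB12). Without the block for the mouse, the pairing of input and IP, m6A counts were 2 and 0 for m6A in brain (VB6 and VB12), 0, 0 and 67 for m6A in liver (VB2, VB6 and VB12), 165 and 145 for m6A in testis (VB6 and VB12), 1, 47 and 67 for differences of m6A between tissues (VB2, VB6 and VB12) and 2165 for enrichment brain against testis. With the replicate number as a block, which pairs expression libraries by number alone, the count was 105 for expression in testis (VB12). Leaving out 1 replicate at a time gave 4 to 19, 44 to 295 and 64 to 222 for expression in liver (VB2, VB6 and VB12), 0 to 2, 19 to 50 and 24 to 98 for expression in testis (VB2, VB6 and VB12), 0 to 1, 3 to 20 and 1 to 14 for m6A in brain (VB2, VB6 and VB12), 0 to 1, 112 to 559 and 465 to 1143 for m6A in liver (VB2, VB6 and VB12), 0 to 2, 245 to 794 and 278 to 814 for m6A in testis (VB2, VB6 and VB12), 5 to 18 and 758 to 1084 for differences of expression between tissues (VB2 and VB12), 12 to 83, 557 to 1670 and 506 to 1392 for differences of m6A between tissues (VB2, VB6 and VB12) and 3002 to 4542 for enrichment brain against testis. Of 92 list tests past the threshold, 7 remained with an estimated correlation and 21 with fry, which passed 27 of all. The VB2 difference in IP over input totals turned its sign when single replicates were left out, to -0.0072 without VB2 replicate 3 and -0.031 without water replicate 1, with a range of -0.031 to 0.076, in brain, 0.015 without VB2 replicate 3 and 0.068 without water replicate 2, with a range of -0.49 to 0.068, in liver, 0.010 without VB2 replicate 2 and 0.17 without water replicate 2, with a range of -0.14 to 0.17, in testis. Same-numbered expression libraries correlated over 0.1 in 19 of 54 pairs across treatments and in 11 of 36 across tissues, with 3 of 3 pairs for testis VB6 and VB12 and for brain and testis of water mice (0.262 to 0.553). The tests between tissues treat libraries of different tissues as independent. The block by number changed no other count by over 1.5 times.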

Other observations

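Further gene groups moved in single members. Of 27 interferon response genes tested for m6A in liver, 1 rose in VB6 and 4 in VB12 (3 up and 0 down in VB6 and 5 up and 0 down in VB12 adjusted over the list alone; camera adjusted p = 0.0116 in VB12, adjusted p = 0.344 with an estimated correlation). Oas2, which activates RNA decay on viral double-stranded RNA, had 2 IP counts over the 3 water libraries, 160 in VB6 and 66 in VB12, with 110, 263 and 146 in input, where all IP counts summed to 6340250, 21821865 and 11323730. In VB2 it had 30 IP counts and 127 in input. It was called in VB12 only. In VB12 testes, m6A was higher for Bag3, a co-chaperone (0.48 ± 0.13, past the threshold in 6 of 14 alternatives), and Sox9, a factor of Sertoli cells (0.54 ± 0.15). It fell there for Tex101, a germ cell surface protein (-0.94 ± 0.11), and Syce3, of the synaptonemal complex of meiosis (-1.28 ± 0.14).

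The splits of the mice reported here were fixed before their results were seen, except those of the liver expression comparisons, which were chosen after. With 3 mice against 3 there are 10 splits, and with 3 input and IP pairs 4, too few for a share under 0.05. For expression, the real split and the highest other gave 0 against 67, 360 against 43 and 364 against 0 genes for VB2, VB6 and VB12 in brain, 15 against 0, 274 against 0 and 263 against 0 in liver and 1 against 1, 47 against 0 and 66 against 1 in testis. For m6A under limma, the values were 0 against 0, 1 against 1 and 0 against 1 in brain, 3 against 2, 263 against 1 and 719 against 1 in liver and 0 against 0, 176 against 1 and 73 against 0 in testis. The number of splits that gave at least as many genes, the real one included, was 2 for VB2 in testis and 2 for m6A of VB6 in brain, and 10 where the real count was 0, and 1 in the other comparisons. Brain mice of VB2 and water gave 67 genes in another split against 0 in the real one, which points to a structure of these samples other than the treatment. For enrichment in water the real and highest other values were 17164 against 2 in brain, 5105 against 0 in liver and 16414 against 0 in testis, and for its differences 9293 against 86 between brain and liver, 3967 against 6 between brain and testis and 8894 against 86 between liver and testis.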
